A study of Mus musculus with 6 samples.

How the data were processed

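RNA of the lens placode (wild type) and of the corresponding surface ectoderm (Pax6-/-) from mouse embryos at embryonic day 9.5 was measured on 6 Illumina bead arrays, 3 per genotype. Per the labels, tissue from 3 embryos was microdissected, RNA of a genotype was pooled, and 3 samples per genotype were amplified to about 6 µg of cDNA and labelled with biotin. Groups and replicate numbers came from the sample titles, and the slide from the chip named in each description. Slide 1 held wild type replicate 1 and Pax6-/- replicates 1 and 2, and slide 2 the other 3 arrays.

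The deposited probe table gave for each array an average signal with a detection p-value per probe, per the file headers. The signals were read as intensities on a linear scale that had not been background-subtracted. It also held other columns, the bead number and the bead standard error, which the authors deposited beside each signal. GenomeStudio is named in the submitters' processing notes, with no version. A second deposited table held the authors' processed intensity values, linear and with values below 0. They ordered the probes of each array as the scanner signals did (rank correlation 1), and their medians on the 3 wild type and then the 3 Pax6-/- arrays were 10.94, 10.95, 10.95, 10.95, 10.95 and 10.93. The background and normalization method behind them is not given in the sources used here.

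From the signals and detection p-values, the background was corrected with limma's neqc method (limma 3.58.1, R 4.3.3), which inferred the negative control distribution from the detection p-values, with an offset of 16, quantile normalization between arrays and log2. Probes were kept where the detection p was under 0.05 on at least 3 of the 6 arrays, which left 21971 of 45281 (48.5%). The offset compresses differences of dim probes, and the filter leaves out probes without changing the difference of those kept. Signals were fitted with lmFit and eBayes, with genotype as the only term, and p-values were adjusted by Benjamini-Hochberg at 0.05. The prior had 2.96 degrees of freedom and the residual 4. Differences are Pax6-/- minus wild type on the log2 scale. Where all arrays of a genotype failed detection, the fold is given as at least the brighter mean over the mean of, per array, the higher of the lowest detected signal and the probe's own value. The same bound is given for some genes detected on only part of the Pax6-/- arrays. The median difference of all genes was -0.07.

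Gene names came from the platform annotation, with symbols looked up through Entrez ids in the GRCm38.p6 gene table. Of the probes, 34885 had 1 symbol, 18 several and 10378 none listed, and 34807 matched an id. No symbol changed. A gene was represented by its kept probe with the highest mean. Of 4586 genes with more than 1 kept probe, 2353 had probes in both directions. No coordinates are printed, since the files name no genome build.

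The design, tests, 20 gene lists and the rule for named genes were fixed before the data were examined. The rule took Pax6, up to 8 genes with the largest positive and 8 with the largest negative difference among called genes whose genotypes did not overlap, and for each list up to 4 called members (lens transcription factor, crystallin, extracellular matrix and Wnt lists) or 2 (others), or, with none called, the member with the smallest p. Since 1 gene was called, this gave Tnc and 1 member of each list. Further genes were named after their values were seen: those past 0.05 adjusted over the list alone, with all arrays or with 1 left out, and some of those under an adjusted p of 0.1 over all probes. Also named so were the list members given as examples that did not pass, the sex-linked genes, Ecm1, and Barx2 and Sema3c.

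Lists with at least 5 measured members were tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. The fit was tested on simulated data for 21971 probes of this comparison: changes of 1, 2, 3 and 4 on the log2 scale were called in 1.20%, 48.0%, 86.4% and 96.4% of 250 probes each, with 3.80 unchanged probes called per run. In a further simulation camera with its preset correlation called 19 of 20 lists shifted by 1, and 4 of 378 unchanged lists. Both simulations drew probes independently, so they give no rate of false list calls for correlated genes. Each probe also had the same spread on all arrays, and falls had no floor. The shares called may thus be too high for these data, where Pax6-/- replicate 2 was dim and a dim probe can fall only to the floor. The correlation estimated in the data was 0.247 for the crystallin list and 0.127 for the endothelial and macrophage list. Alternatives covered background correction, normalization, the authors' values, the detection filter, slide and replicate number as blocks, array weights, the variance prior, each array left out, the probes behind a gene, the test per probe and the list test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No control probes were used here, and no arrays were left out of the main comparison.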

Results

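Gene expression was measured in the tissue that forms the eye lens of mouse embryos at embryonic day 9.5. The lens placode of wild type embryos, a thickened patch of surface ectoderm lying over the optic vesicle, was compared with the corresponding surface ectoderm labelled Pax6-/-. Pax6 is a transcription factor needed for eye development. Tissue was cut by laser microdissection from frozen sections of 10 µm. Per the labels, RNA from 3 embryos of a genotype was pooled and amplified in 3 separate samples, each hybridised to 1 Illumina bead array, giving 3 wild type and 3 Pax6-/- arrays. The p-values therefore measure only the spread between these samples. By the labels this spread may be technical, but Xist on Pax6-/- replicate 2, described below, argues against one shared pool for that array. Of the 45281 probes, 21062 to 22712 were detected on 5 of the arrays and 17276 on Pax6-/- replicate 2, whose mean signal was 182 against 228 to 260 on the others. The number of arrays limits the precision: the median standard error of a log2 difference was 0.38.

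The targeted gene was examined first. Both Pax6 probes gave lower signal on all 3 Pax6-/- arrays than on any wild type array. On the brighter probe the wild type arrays read 11.10, 11.07 and 11.17 on the log2 scale and the Pax6-/- arrays 10.26, 10.79 and 10.31. The log2 difference was -0.66 (SE 0.27), or 1.58-fold lower, and did not pass the test over all probes (adjusted p = 0.528). On the other probe the wild type arrays lay between 10.84 and 11.21 and the Pax6-/- arrays between 9.95 and 10.39. Pax6 transcript was thus well detected on all 6 arrays. The allele, the deleted part of the gene and the position of the probes in it are not given in the sources used here, and a probe outside the deleted part does not check the labels.

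The comparison asked which genes of the early lens depend on Pax6. Tnc, which encodes the extracellular matrix glycoprotein tenascin C, was at least 25.1-fold lower in Pax6-/- tissue on its brightest probe. That probe had a log2 signal of 9.75 ± 0.29 in wild type and 4.89 ± 0.15 in Pax6-/- (SD, n = 3). It was detected on all 3 wild type arrays and on 1 of the Pax6-/- arrays, so the fold is given against the lowest detected signal. Its fitted log2 difference was -4.86 (SE 0.27, adjusted p = 0.00582), and Tnc was the 1 gene called among 10967 tested. Of 5 kept Tnc probes 4 were lower, and the other was high on Pax6-/- replicate 2 alone, at 7.85. A second probe fell about as far as the brightest, from 9.40 to 9.92 in wild type to 4.71 to 5.08 in Pax6-/-. The remaining lower probes do not show a fall of this size. They were dim even in wild type, at 4.85 to 7.38, and were not detected on any Pax6-/- array. Lens genes had large negative differences that did not pass the threshold: the gamma crystallin Cryge had a fitted difference of -3.61 (SE 0.38, adjusted p = 0.0832) and the lens fibre regulator Maf of -2.59 (SE 0.28, adjusted p = 0.0885), and both were lower on all 3 Pax6-/- arrays than on every wild type array. Cryge was detected on 1 and Maf on 2 of these arrays, and against the lowest detected signal they were at least 9.11-fold and 5.62-fold lower. As a group, crystallins and lens fibre genes were shifted down (adjusted p = 0.00241 by camera), a shift that did not pass with an estimated correlation (adjusted p = 0.538).

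**Figure D1:**
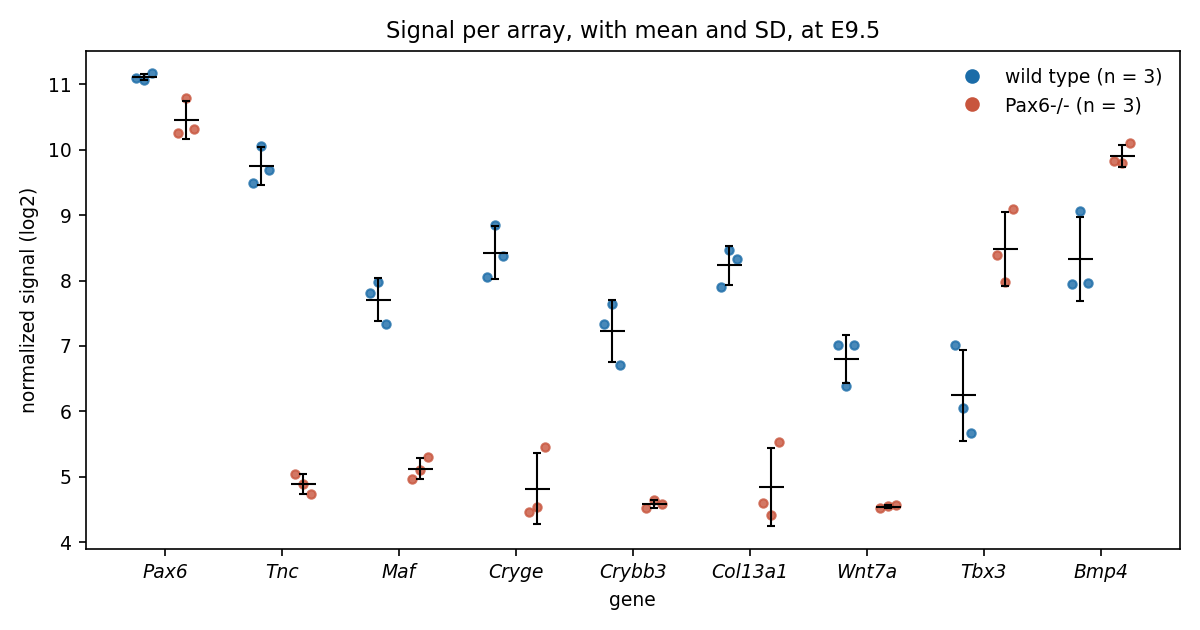
Normalized log2 signal of 9 genes (vertical axis) on each array, with wild type in blue and Pax6-/- in red, 3 arrays each; each dot is 1 array, the horizontal bar the mean and the error bar the SD. Tnc lies between 9.48 and 10.06 in wild type and between 4.73 and 5.04 in Pax6-/-, and the Pax6 values of the genotypes lie closer together than those of any other gene shown.

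Over all 21971 probes tested, limma called 2 at an adjusted p under 0.05, both of Tnc and both lower, and no probe higher. At an unadjusted p under 0.05 there were 2034 probes, 1147 lower and 887 higher, where 1098.6 would pass by chance. In 1916 genes, or 17.5%, the arrays of the genotypes did not overlap, where chance gives 10%, with 791 higher and 1125 lower in Pax6-/-. The call of Tnc was lost with the slide as a block (adjusted p = 0.0653, log2 difference -4.83), where it was -4.52 within slide 1 and -5.15 within slide 2. It was also lost without wild type replicate 1 (adjusted p = 0.0730, log2 difference -5.01), 2 (0.0747, -4.65) or 3 (0.101, -4.87) and without Pax6-/- replicate 3 (0.0702, -4.79), with 0 genes called in each case. Averaging all kept probes of a gene called 21 genes, 19 lower and 2 higher, that did not include Tnc (adjusted p = 0.0648, log2 difference -2.29).

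Among the lens lineage transcription factors, 15 of 22 were measured, 8 higher and 7 lower, and none passed the test over all probes. Adjusted over the list alone, 4 were lower: Maf, Prox1, a homeodomain factor of lens fibre differentiation (-1.43, SE 0.41), Pitx3, needed for lens development (-1.33, SE 0.33), and Mab21l1, which is needed for lens formation (-1.10, SE 0.24). Pitx3 was not detected on any Pax6-/- array and was at least 1.92-fold lower. Such a bound sets the wild type mean against the lowest detected signal of the Pax6-/- arrays. Other members had positive differences that did not pass, among them Meis2 at 0.69 and Dach1 at 1.01, which was 0.55 without wild type replicate 2. The list as a whole was not called by camera (adjusted p = 0.632) or by fry (adjusted p = 0.111). Its median of 0.11 and mean of -0.31 differed in sign. Without Pax6-/- replicate 2 the median was -0.24, with 7 higher and 8 lower, and Prox1, at -1.31, no longer passed (adjusted p = 0.105 over the list alone). Prox1 also did not pass without wild type replicate 1 or 3 or Pax6-/- replicate 1 (adjusted p = 0.090 to 0.107 over the list alone).

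Of 26 crystallins and lens fibre genes, which encode the structural proteins of the lens, 10 were measured, 9 lower and 1 higher, with a median log2 difference of -0.68, or -0.54 with undetected members at their bound. None passed over all probes. Adjusted over the list alone 5 were lower, with fitted differences in brackets: Cryge, Crybb3 (-2.64, SE 0.31), Crygd (-2.37, SE 0.54), Crygb (-1.77, SE 0.52) and Crygc. Crybb3 was not detected on any Pax6-/- array and was at least 4.54-fold lower, and Crygc likewise at least 1.65-fold lower. Cryab, Cryba4 and Mip (-0.10, -0.07 and 0.44) depended on single arrays: leaving out 1 array gave -0.58 to 0.47 for Cryab, -0.48 to 0.28 for Cryba4 and 0.03 to 1.02 for Mip. The dim array, Pax6-/- replicate 2, had the lowest median of this list after each gene was centred on its mean. Without it 3 members were higher and 7 lower, and Crygb, at -1.74, no longer passed (adjusted p = 0.0608 over the list alone). The list was then called by camera with the preset correlation (adjusted p = 0.0271) but not with an estimated correlation (adjusted p = 0.796). Crygd and Crygb were each detected on 1 Pax6-/- array and were at least 4.24-fold and 2.68-fold lower. The fitted Crygd difference was -1.78 without wild type replicate 2. Crygb also did not pass without wild type replicate 2 or 3 or Pax6-/- replicate 3 (adjusted p = 0.072 to 0.091 over the list alone).

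Of 34 extracellular matrix genes, 30 were measured, 16 higher and 14 lower, and Tnc was the 1 member past the threshold over all probes. Adjusted over the list alone there were 3 lower: Tnc, the transmembrane collagen Col13a1 (fitted difference -3.39, SE 0.37, adjusted p = 0.0885 over all probes), which was detected on 1 Pax6-/- array and was at least 7.84-fold lower, and the hyaluronan synthase Has2 (-1.36, SE 0.28). When 1 array other than Pax6-/- replicate 2 was left out, Has2 lay between -1.40 and -1.25 and did not pass (adjusted p = 0.051 to 0.106 over the list alone). Fn1, fibronectin, did not pass, at -0.40. Neither did the main collagens and laminins of basement membranes, with Col4a1 at 0.15 (0.04 without wild type replicate 3) and Lama1 at -0.60 (-0.20 without Pax6-/- replicate 1, -1.10 without replicate 2). The list was not called by camera (adjusted p = 0.994). Fry asks whether the members move one way on balance and does not set them against other genes. It called the list down (adjusted p = 0.0361). Of 32 genes of epithelial shape and adhesion 28 were measured, 14 in each direction, with none past either threshold. The smallest p among them was that of the planar polarity gene Vangl2 (0.53, SE 0.26).

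Genes of signalling pathways gave values in both directions. Of 31 Wnt pathway genes measured, 2 were lower adjusted over the list alone, the ligand Wnt7a (-2.26, SE 0.28) and the secreted modulator Dkk3 (-1.11, SE 0.24). Wnt7a was not detected on any Pax6-/- array and was at least 3.39-fold lower (adjusted p = 0.0951 over all probes). Of 21 BMP and TGF-beta genes measured, 2 were higher adjusted over the list alone, the T-box factor Tbx3 (2.24, SE 0.46) and the ligand Bmp4 (1.58, SE 0.37), and each lay higher on all 3 Pax6-/- arrays than on every wild type array. Tbx3 lay between 1.95 and 2.31 without wild type replicate 2 or 3 or Pax6-/- replicate 1 or 3, and did not pass there (adjusted p = 0.083 to 0.161 over the list alone). A second Bmp4 probe had the opposite sign. Without Pax6-/- replicate 2, Dkk3 (-1.07, adjusted p = 0.0580) and Bmp4 (1.63, 0.0626) no longer passed over their lists, with differences about as large. This was not particular to that array. When each array was left out in turn, Dkk3 passed only without Pax6-/- replicate 3 (adjusted p = 0.0443 over the list alone). Bmp4 passed only without wild type replicate 2 (adjusted p = 0.0122 over the list alone). In the FGF list the ETS factor Etv1 was lower (-1.71, SE 0.32) as 1 of 16 measured, and in the retinoic acid list the synthesis enzyme Aldh1a3 (-1.14, SE 0.28) as 1 of 11, both adjusted over the list alone and not over all probes. When 1 array other than Pax6-/- replicate 2 was left out, Etv1 lay between -1.78 and -1.55 and did not pass (adjusted p = 0.067 to 0.093 over the list alone). Aldh1a3 was at -1.18 without Pax6-/- replicate 2 and no longer passed (adjusted p = 0.0714 over the list alone). When each array was left out in turn, Aldh1a3 passed only without Pax6-/- replicate 3 (adjusted p = 0.0333 over the list alone). With all arrays no Notch gene passed either way among 13 measured, with 11 lower and 2 higher, Notch1 at 1.23 (SE 0.29) among the latter, which passed over the list alone without wild type replicate 2 (1.40, adjusted p = 0.0450). Without Pax6-/- replicate 2, 4 further members passed over their lists: the Notch ligand Jag1, lower (-1.51, adjusted p = 0.0199), and Tgfb3 (1.32, 0.0237), Spred3 of the FGF list (1.44, 0.0199) and Dlx2 of the mesenchyme list (1.98, 0.00849), higher. None of these lists was called by camera, with adjusted p of 0.587 for Wnt, 0.380 for BMP and TGF-beta, 0.994 for FGF, 0.275 for Notch and 0.678 for retinoic acid.

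No list of ectodermal markers was called. Of 23 surface ectoderm and keratinocyte markers measured, 18 were higher and 5 lower, with a median of 0.14 and none past either threshold (camera adjusted p = 0.216). Without Pax6-/- replicate 2 the members were 12 higher and 11 lower. The keratin Krt14 had the smallest p among them (0.81, SE 0.33). Among 12 markers of other placodes and facial ectoderm, the forkhead factor Foxi2 was higher adjusted over the list alone (1.40, SE 0.30). Without Pax6-/- replicate 2 its difference was 1.37, which did not pass (adjusted p = 0.0692 over the list alone). When each array was left out in turn, Foxi2 passed only without wild type replicate 1 (adjusted p = 0.034 over the list alone). The list was not called by camera (adjusted p = 0.587).

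Markers of neighbouring cell types were read from the same arrays. Endothelial and macrophage markers were shifted down (9 measured, 7 lower and 2 higher, median -1.15, camera adjusted p = 0.0391). The shift did not pass with an estimated correlation (adjusted p = 0.538), with the slide as a block (0.0864) or without Pax6-/- replicate 2 (0.153, median -1.05). Adjusted over the list alone 2 were lower, the receptor partner Ramp2 (-1.40, SE 0.34) and the endothelial factor Sox17 (fitted difference -2.12, SE 0.60). Without Pax6-/- replicate 2 they were at -1.25 and -1.80, and neither passed (adjusted p = 0.0776 and 0.0909 over the list alone). With any 1 wild type array left out neither passed (adjusted p = 0.0674 to 0.1115 over the list alone), nor did Sox17 without Pax6-/- replicate 1 (0.0856). Without Pax6-/- replicate 3 the fitted Sox17 difference was -2.81 (adjusted p = 0.00116 over the list alone). Ramp2 was detected on 2 Pax6-/- arrays and Sox17 on 1, and they were at least 2.21-fold and 3.13-fold lower. Of 17 periocular mesenchyme and neural crest markers measured, 2 were lower adjusted over the list alone, Pdgfra (-1.89, SE 0.33) and Col6a2 (-1.60, SE 0.24), the latter undetected on all Pax6-/- arrays and at least 2.41-fold lower. The list was not called by camera (adjusted p = 0.853). Of 11 optic vesicle and neural markers measured, 6 were higher and 5 lower, none past either threshold with all arrays (median 0.36, adjusted p = 0.380). Pax2 varied from 6.93 to 9.92 among the Pax6-/- arrays, and its difference was 3.26 without Pax6-/- replicate 1, where it passed over the list alone (adjusted p = 0.0256), and 1.73 without Pax6-/- replicate 2. All 9 primitive erythroid markers measured had negative differences (median -0.72), with Klf1 undetected on all Pax6-/- arrays, and the list did not pass (adjusted p = 0.216). Without Pax6-/- replicate 2 the median was -0.10, with 2 higher and 7 lower, and within slide 1 it was 0.13. Embryonic globin signal varied within each genotype: Hba-x read 10.95, 7.66 and 8.49 on the Pax6-/- arrays and 9.17, 10.70 and 9.91 on the wild type arrays.

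**Figure D2:**
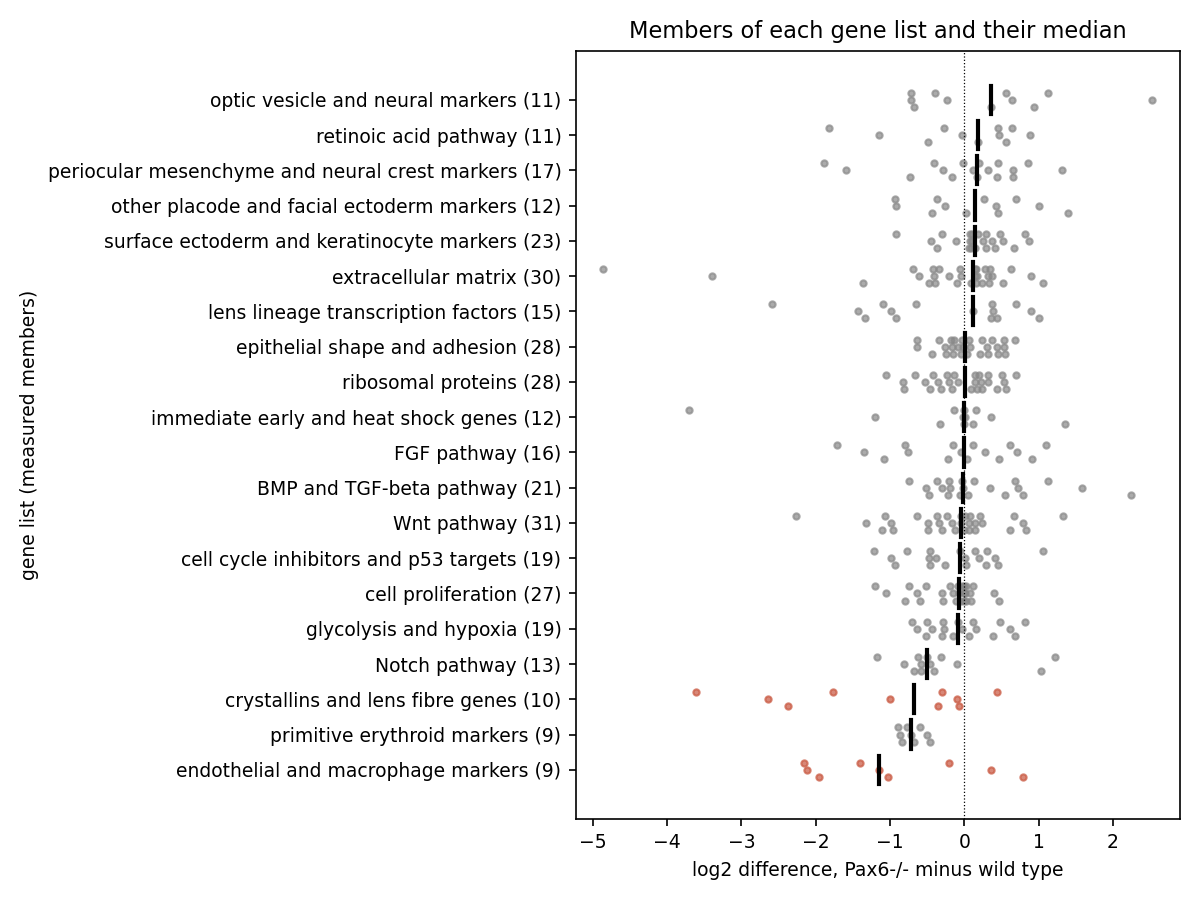
Log2 difference, Pax6-/- minus wild type (horizontal axis), of each measured member of the 20 gene lists (vertical axis, with the number measured); each dot is 1 gene, the black bar the median, and red marks the 2 lists called by camera with its preset correlation. Crystallins and lens fibre genes have a median of -0.68 and endothelial and macrophage markers of -1.15, and most other lists spread to both sides of 0.

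No list of growth and stress genes was called by camera. Camera gave adjusted p of 0.587 for 27 cell proliferation genes, 0.632 for 19 cell cycle inhibitors and p53 targets, 0.994 for 19 glycolysis and hypoxia genes and 0.675 for 28 ribosomal protein genes, with no member past either threshold. Of the 28 ribosomal protein genes, 9 were higher and 3 lower in Pax6-/- without overlap of the genotypes, where 17.5% of all genes had no overlap. The smallest p in each was that of Ube2c (-1.05, SE 0.40), Sesn1 (-0.98, SE 0.30), Slc2a3 (0.82, SE 0.29) and Rpl22 (-0.81, SE 0.34), and Ube2c was at -0.65 without Pax6-/- replicate 2. Among 12 immediate early and heat shock genes, adjusted over the list alone, Egr1 was lower (fitted difference -3.70, SE 0.60) and Junb higher (1.36, SE 0.34). Egr1 was detected on 1 Pax6-/- array and was at least 10.5-fold lower against the lowest detected signal. Its fitted difference was -3.05 without wild type replicate 2 and -4.35 without wild type replicate 1. The list was not called by camera (adjusted p = 0.994). Of the 25 members past the threshold within their lists, 10 passed whichever array was left out: Maf, Cryge, Crybb3, Crygd, Tnc, Col13a1, Wnt7a, Col6a2, Pdgfra and Egr1. Further members passed within their lists when another array was left out: Sox2, lower, without wild type replicate 1; Notch1, higher, and Esam, lower, without wild type replicate 2; Mip and Pax2, higher, without Pax6-/- replicate 1; Sfrp2, Wnt5b, Stra6 and Cldn5, lower, and Tek, higher, without Pax6-/- replicate 3. Over the 20 lists, camera with its preset correlation called 2, both down, and with an estimated correlation 0. At an unadjusted p under 0.05 it gave 4. Fry called 1 list, and its mixed test, which counts changes in either direction together, called 12, among them extracellular matrix (adjusted p = 7.83e-06) and lens lineage transcription factors (0.000307). The median, mean and test differed in sign in 7 lists: lens lineage transcription factors, extracellular matrix, BMP and TGF-beta, FGF, retinoic acid, immediate early and ribosomal.

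Sex-linked transcripts differed within the Pax6-/- group, in genes chosen after their values were seen. All 4 probes of Xist, the RNA that silences an X chromosome in female cells, lay between 10.05 and 11.68 on Pax6-/- replicate 2 and at or below 4.90 on the other 5 arrays. Of the 4 probes of the Y-linked genes Eif2s3y, Kdm5d and Uty that were detected on all 5 other arrays, 1 was detected on Pax6-/- replicate 2. The brighter Eif2s3y probe read 4.55 there and from 8.23 to 8.90 elsewhere. The same array also had the lowest correlations with the others over the tested probes, from 0.797 to 0.825, where the remaining pairs ranged from 0.878 to 0.957. Without this array limma called the same number of probes, 2, and the Pax6 difference was -0.82 (SE 0.22).

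**Figure D3:**
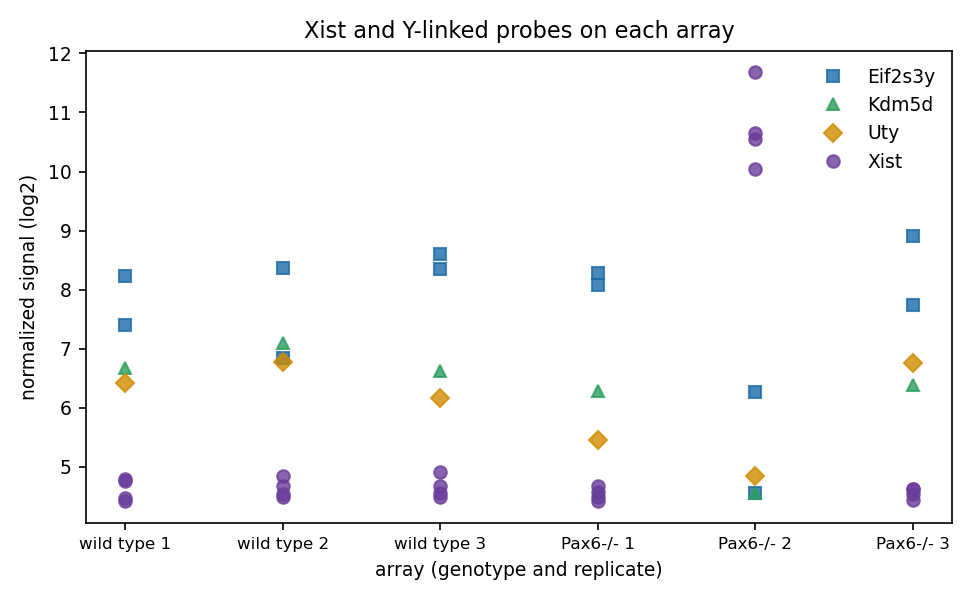
Normalized log2 signal (vertical axis) of the 4 Xist probes and of the 4 Y-linked probes detected on all other arrays, on each of the 6 arrays (horizontal axis); each symbol is 1 probe. Xist exceeds 10 on Pax6-/- replicate 2 alone, at 10.05 to 11.68, and the Y-linked probes have their lowest values on that array, the second Eif2s3y probe staying at 6.27.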

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

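The authors' values with 16 added and the threshold of 0.1 were chosen after seeing the data, as were the folds against the floor and the members left within lists when an array was left out. Of 25 members past the threshold within their lists, 11 to 17 still passed without 1 array, and 0 to 5 others passed newly. The Pax6 difference stayed between -0.82 and -0.56 and short of the threshold in all 19 alternatives. Tnc was negative in 19 alternatives, from -5.97 to -2.29, with adjusted p from 0.00270 to 0.278, and was called in 12. A filter on all 6 arrays removed it. Over genes and lists, 767 of 828 alternative values kept direction and side of the threshold, 10 passed it newly, 19 no longer passed, and 32 turned direction, 0 of them past the threshold on either side. Dim signal over background limits the genes that matter most here, since Tnc, Cryge and Maf lay near the floor in Pax6-/-. The cause was not tested for any change below unless stated.

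The main settings called 2 probes, 1 gene (also 1 of at least 2-fold) and 2 lists. The authors' values floored at 1 called 47 probes (7 higher, 40 lower) and 25 genes, all at least 2-fold, and with 16 added 4 probes and 3 genes. No filter gave 6 probes, 5 genes and 0 lists, detection p under 0.01 on 3 arrays 5 probes, 4 genes and 1 list, and detection on all 6 arrays 0 probes, 0 genes and 0 lists. Array weights gave 17 probes (2 higher, 15 lower), 12 genes and 1 list, and the trend and robust prior 4 probes and 3 genes. In each of these the count of genes at least 2-fold was the same as that of genes. The mean of a gene's probes gave 21 genes (2 higher, 19 lower), all at least 2-fold, with fewer tests to adjust for. The 0.1 threshold gave 23 probes, 20 lower and 3 higher. An unmoderated test per probe called 1 probe with equal and 0 with unequal variances. Scaling to the 75th percentile called 1 list, an estimated correlation 0 and fry 1. Leaving out 1 array gave 0 to 2 probes, 0 to 1 genes, 0 to 1 of at least 2-fold and 1 to 3 lists.

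With the slide as a block 0 probes, 0 genes and 1 list were called. With the replicate number as a block the counts were 0 probes, 0 genes, 0 at least 2-fold and 1 list. Same-numbered arrays did not deviate together (correlations 0.0559, 0.0451 and 0.0185), although the arrays numbered 1 shared slide 1 and those numbered 3 shared slide 2.

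The authors' values floored at 1 moved the median of all genes to -0.114 and the 0.01 filter to -0.101, from -0.07. The adjusted p of lists that turned direction were as follows. FGF gave 0.961 without background correction, 0.965 with normexp, 0.944 with 75th percentile scaling, 0.961 with cyclic loess, 0.735 with the 0.01 filter, 0.736 with detection on all arrays, 0.860 with the slide block, 0.936 with weights and 0.510 with fry. Extracellular matrix gave 0.969 with the 0.01 filter, 0.704 with all arrays, 0.994 with the replicate block and 0.951 with the robust prior. Lens transcription factors gave 0.736 with all arrays and 0.951 with the robust prior. Immediate early genes gave 0.982 with cyclic loess, 0.886 with the slide block, 0.994 with the replicate block and 0.884 with weights. Ribosomal proteins gave 0.856 with 75th percentile scaling, glycolysis 0.994 with the replicate block, and periocular mesenchyme 0.510 with fry. With 1 array left out the ranges were 0.818 to 0.978 for extracellular matrix and for immediate early genes, 0.746 to 0.978 for FGF, 0.390 to 0.992 for retinoic acid, 0.609 to 0.963 for periocular mesenchyme and 0.895 to 0.978 for glycolysis. Erythroid markers were called without wild type replicate 1 or Pax6-/- replicate 1 (lowest adjusted p 0.000214, range up to 0.850). Crystallins were called in 18 of 21 alternatives and endothelial markers in 11 of 20, all of them by camera with its preset correlation. Crystallins did not pass without a filter, with an estimated correlation (adjusted p = 0.538) or by fry (adjusted p = 0.0626).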

Other observations

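The tests on Pax6 and on the sex-linked genes were chosen after those values were seen, and so was the count of genes detected in 1 genotype alone. The margins of the 2 tests that use the fall of the Y-linked probes, and the test for wild type samples, were changed after earlier results were known. The splits of the arrays were planned.

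Some genes, many of them outside the lists, were detected in 1 genotype alone. With detection p under 0.01 on all 3 arrays of a genotype and no detection at 0.05 on the other 3, there were 27 genes for wild type and 5 for Pax6-/-. Among the other 9 splits of the 6 arrays the highest count on 1 side was 10, though Pax6-/- replicate 2 detected fewer probes than any other array, which adds to the wild type count. The ubiquitin-like interferon-induced gene Isg15 was at least 11.8-fold lower in Pax6-/-, the membrane-bound chemokine Cx3cl1 at least 6.21-fold, the odd-skipped factor Osr2 at least 5.10-fold, the fatty acid elongase Elovl3 at least 5.01-fold and Islr2 at least 4.96-fold, with adjusted p of 0.0951, 0.0715, 0.0605, 0.0605 and 0.0538, so none passed the threshold. In the other direction Ecm1, extracellular matrix protein 1, was at least 4.96-fold higher (adjusted p = 0.202). When all kept probes of a gene were averaged, the homeobox gene Barx2 (1.98, adjusted p = 0.0402) and the guidance ligand Sema3c (2.57, adjusted p = 0.0338) were the 2 called higher. On their brightest probes they differed by 1.66 and 1.86, with adjusted p of 0.150 and 0.190.

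Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split was the 1 of 10 with the largest value for each count: 2 probes called against a highest other of 0, 1 gene called against 0, 1 gene of at least 2-fold against 0, 2 lists against 1, and 1916 genes with separate genotypes against 1303.

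Pax6-/- replicate 2 carried Xist and little Y-linked signal. Amplifications of one pooled RNA would share these transcripts, and the smallest Xist gap to the other Pax6-/- arrays was 5.42 (log2). This argues against one shared pool for this array. The low signal of this array was argued against for Xist, whose median rise of 6.14 lay at percentile 100 of 10000 random lists matched on level, and by a small margin for the Y-linked probes, whose median fall of -1.71 lay at percentile 2.25 of 10000 lists and 1.92 of 200000. A wrongly labelled wild type sample was argued against on 100 genes chosen without this array. The array lay at a median of 0.964 of the way from wild type to Pax6-/-, and at 0.730 on those higher in Pax6-/-. Wild type arrays left out in the same way reached 0.174 and 0.272. Quantile normalization can lift bright probes on a dim array: a Pax6 probe with a signal of 1029 here and 1051 on Pax6-/- replicate 1 became 10.36 and 9.95. The low signal of this array may therefore add to these places. RNA from female embryos alone did not meet the criterion written for it, no Y-linked probe detected, as 1 of 4 was, an Eif2s3y probe whose match to the X-linked copy was not analysed here. Female cells mixed into a male sample may remain, and the median fall of -1.71 sets no bound on their share, since undetected probes stop at the floor. Against the lowest detected signal, the brighter Eif2s3y probe was at least 8.49-fold lower than on the other arrays, Kdm5d at least 2.33-fold and Uty at least 1.89-fold. Taken alone, that Eif2s3y probe would leave male RNA a small part of this sample. The other Eif2s3y probe, however, was detected here at 6.27, 2.66-fold below the other arrays. The share of male RNA is therefore not settled by these probes.

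Pax6 signal stayed high in Pax6-/-, with a log2 difference of -0.66. A wild type sample among the Pax6-/- arrays was argued against by the same places, the lowest of the 3 being 0.602 on all 100 genes (0.387 on those higher in Pax6-/-), and background by the Pax6 probes standing at least 4.97 above the lowest detected signal. Optic vesicle cells express Pax6 in wild type embryos. Whether these cells also carry the deletion in the Pax6-/- embryos is not given in the sources used here. If they do, they would add signal only if the allele leaves a transcript, which is unknown. They cannot be told apart from other sources, because the median of their markers (0.36) covered members in both directions. The 2 probes differed by 0.10 in their log2 differences, which cannot place them inside or outside the deleted part, so a persisting transcript that lacks function may remain, untested.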
